A study of Mus musculus with 4 samples.

How the data were processed

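The samples were 4 RNA-seq libraries labelled as mouse spleen CD4+ T cells, 2 labelled WT and 2 labelled Mthfd2 KO. Cd8a stood at between 3.10 and 4.00 times the level of Cd4 in every library, which goes against the label of CD4+ cells. Results on T cell genes are therefore not known to be those of CD4+ T cells. Per the labels, the T cells carried the TEa receptor transgene, were purified by positive magnetic selection from 8-week-old mice and were cultured for 3 days with mitomycin-treated spleen cells of F1 mice as antigen-presenting cells. Total RNA was treated with DNase and depleted of ribosomal RNA before fragmentation and cDNA synthesis, per the labels' protocols. The labels do not say whether the 2 libraries of a group came from separate animals or cultures. P-values of single genes therefore measure the spread between these libraries, which may be technical.

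The authors deposited 1 table per library with whole-number read counts for 31748 gene symbols, not normalized. Subread 2.0.1 with featureCounts, the mm10 genome build, R 4.0.4 and DESeq2 1.30.1 are named in the submitters' processing notes. The aligner, the annotation release, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Reads of near-identical copies and of antisense partners could therefore not be told apart. Rows of ribosomal protein pseudogenes held between 1.87% and 2.24% of the counts of a library. Genes with many processed copies, among them ribosomal protein genes, Gapdh and other enzymes of glycolysis, are uncertain for this reason. No column of per-sample values was left unused, and each row named a gene. Of the symbols, 31345 were found in a RefSeq table of assembly GRCm38.p6 and 403 were not. Positions were taken from the GENCODE annotation of GRCm38, the assembly called mm10, and all coordinates are counted from 1.

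Total counts ranged from 14191401 to 15955863 per library. The libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 40.3 between the WT libraries over 12620 genes and of 16.1 between the KO libraries over 12502 genes. Neither pair therefore looks like 1 library deposited again. They were counted as separate samples because the labels list them so, though repeat preparations of 1 sample could differ as much. The most abundant gene held 0.797% of the counts in WT replicate 1 and between 0.907% and 1.26% in the other libraries, and the 10 most abundant genes held between 4.68% and 5.46%.

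Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 12752 genes, and libraries were scaled by TMM with factors between 0.968 and 1.027. KO was compared with WT by edgeR's quasi-likelihood test at the defaults of this version, with all 4 libraries and no covariate. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are KO over WT on the log2 scale, each with its standard error (SE) and n = 2 libraries per group. CPM values are counts scaled to the TMM-adjusted library total. The fitted prior degrees of freedom were 4.70 and the common biological coefficient of variation was 21.4%.

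The fit was tested on simulated counts with the means, library sizes and dispersions of this comparison, in which 12472 genes passed the filter. It called 35.1% of 97 genes changed 2-fold and 85.9% of 99 genes changed 4-fold, and 20 of 12276 unchanged genes. Many changes of 2-fold or less were therefore missed in this simulation. It changed few genes and gave both groups the same dispersion, while the WT pair was more spread than the KO pair. Its rates may therefore not be those of the real comparison. The unchanged genes also made up a larger share of the simulated calls than the threshold on the adjusted p is meant to allow. False calls among the genes called in the real libraries may therefore be more frequent than that threshold states.

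Before the data were examined, 40 gene lists with 799 entries were fixed, covering folate and nucleotide metabolism, stress responses, energy metabolism, cell cycle, T cell states and other cell types a spleen culture could hold. Of these entries, 795 were matched to the tables, 33 of them through an older symbol and 13 mitochondrial genes by hand, and 4 were not matched. The lists with at least 3 kept members, 39 of the 40, were tested by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and a two-sided test, adjusted by Benjamini-Hochberg over the lists. A list was called at an adjusted p under 0.05. At the preset correlation camera sets the members of a list against all other genes. Its p-values then rest mainly on the spread between genes and do not measure the spread between libraries. For each list, members called in the edgeR test are counted over all genes tested and, separately, adjusted over the list alone. None of the list calls held when camera estimated the correlation of each list from these 4 libraries: the smallest adjusted p was then 0.736. Only 2 residual degrees of freedom enter that setting, so it has little power and cannot decide for or against a list. The self-contained test fry, which asks whether the genes of a list move on balance in 1 direction, gave a smallest adjusted p of 0.223 and 5 lists at an unadjusted p under 0.05.

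Named genes followed a rule fixed before the data were examined. It took Mthfd2, then the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 5 CPM and both KO libraries on 1 side of both WT libraries, leaving out predicted genes, pseudogenes and segments of antigen receptors. It also took up to 4 members with the smallest p from each list, or for lists of other cell types the 3 members with the highest mean CPM. Genes named beyond the rule, among them further called members of lists, Hif1a, Adm, Vegfa, Hk2, Gapdh, Mki67, Cd4, the T cell receptor segments, H2-Ea and the genes induced by LXR, were chosen after their values were seen. Some genes that the rule takes are not reported here.

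The alternatives tried were other scalings (DESeq2 size factors, upper quartile, library size), other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter thresholds, other list tests and leaving out each library in turn. The planned edgeR setting legacy=TRUE turned out to be the default of the installed version, so its counterpart legacy=FALSE was added after the data were seen. Intervals for shares of counts are exact binomial (Clopper-Pearson) 95% intervals. They cover counting error only, since reads amplified by PCR are not independent molecules.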

Results

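Transcriptomes were measured in libraries labelled as TEa T cells after a 3-day culture with F1 (BALB/c x C57BL/6) spleen cells. TEa cells are CD4+ T cells whose transgenic receptor recognises a peptide of the BALB/c class II chain I-E alpha presented by the C57BL/6 molecule I-A, so the culture described by the labels models the response to a foreign graft donor. The T cells were labelled either wild type (WT, 2 libraries) or as lacking Mthfd2 (KO, 2 libraries). By the labels, the comparison asks which transcripts depend on Mthfd2, a mitochondrial enzyme of folate one-carbon metabolism, in T cells responding to alloantigen. Trbv19, the beta segment of the TEa receptor, held at most 8.39% of Trbv counts in a library. H2-Ea, which encodes I-E alpha, had at most 2 counts. The results are therefore not known to be those of TEa cells responding to alloantigen. WT replicates 1 and 2 held 15955863 and 14686711 counts, and KO replicates 1 and 2 held 14191401 and 14419298. A count was present for between 15364 and 16301 genes per library. The first principal component of the kept genes held 69.0% of the variance. WT replicate 1 lay at -65.1 on it, WT replicate 2 at -19.6, and the KO libraries at 43.8 and 40.9, so the WT libraries lay farther apart than the KO libraries.

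Mthfd2 itself was expressed in all libraries. It lies on the minus strand of chromosome 6 (GRCm38, 83305691 to 83325908, gene ENSMUSG00000005667.8), and its transcript 201 has 8 exons. Its level was 280 ± 0.450 CPM in WT libraries and 237 ± 20.6 CPM in KO libraries (SD, n = 2 each), from 4581 and 4149 counts in WT replicates and 3146 and 3510 in KO replicates. The log2 fold change was -0.24 ± 0.14 (SE), and the difference was not past the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.324). The labels do not say which part of the gene was deleted, and a count over the whole gene cannot check the loss of some exons. The directions given here for KO over WT therefore rest on the submitters' labels.

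Of 12752 genes tested, 305 were higher and 199 lower in the KO-labelled libraries. A change of at least 2-fold was found for 244 of the higher and 163 of the lower genes. The median log2 fold change over all tested genes was near 0 (-0.0026). The 12 genes with the largest rise included 2 of the glycolysis list (Aldoc and Slc16a3) and 2 of the hypoxia list (Bnip3 and P4ha2). The 12 with the largest fall included Il2, Il22, Ifng and Lta of the T cell lists, Isg15 of the interferon list, and Hba-a2 and Jchain of the lists of other cells. With a single KO library left, the spread comes from the WT pair alone. The edgeR test then called 0 genes without KO replicate 1 (1566 at an unadjusted p under 0.05) and 0 without KO replicate 2 (2097 at an unadjusted p under 0.05), so 0 members of each list passed that test over all genes there too. The median log2 fold change of the 199 lower genes was -1.32 with all libraries, -1.33 without KO replicate 1 and -1.39 without KO replicate 2. Their median SE went from 0.23 to 0.30 and 0.31. None of the 504 calls changed sign. In all 504, both KO libraries lay on 1 side of both WT libraries, so leaving out a library could hardly turn a sign. When WT replicate 1 was left out, 314 genes were higher and 134 lower, 164 of the 504 calls were lost, and 235 higher and 88 lower genes changed at least 2-fold. Without either WT library the spread comes from the KO pair alone, which lay closer together. Without WT replicate 2 the WT group is replicate 1 alone, the library that lay apart. Counts of calls from these fits, here and below, are therefore not stronger evidence than those with all libraries. Without WT replicate 2 the median log2 fold change was 1.55 for the 305 higher and -1.50 for the 199 lower genes. With all libraries DESeq2 called 854 higher and 779 lower.

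Among the 12 genes with the largest rise, 3 were almost silent in WT libraries. Mgarp, a protein of mitochondria, had 0 and 2 counts in WT libraries and 286 and 145 in KO libraries, a ratio of 239 (95% counting interval 65.8 to 1980). Vldlr, a receptor for very-low-density lipoprotein, had 0 and 2 counts in WT and 244 and 138 in KO libraries, a ratio of 212 (95% counting interval 58.3 to 1756). Itga7, an integrin alpha chain, had 0 and 4 counts against 394 and 231 (log2 fold change 7.34 ± 0.73, adjusted p = 0.0199). Slc16a3, the lactate exporter MCT4, rose from 13.1 and 37.7 CPM to 437 and 359 CPM (3.98 ± 0.48, adjusted p = 0.0241; chromosome 11, 120948480 to 120960868). Bnip3, a receptor for the removal of mitochondria, rose by 4.07 ± 0.43 and Ak4, a mitochondrial adenylate kinase, by 3.81 ± 0.30. Aldoc (aldolase C), Fads2 (a fatty acid desaturase), P4ha2 (a prolyl hydroxylase subunit of collagen synthesis), Epas1 (the hypoxia-inducible factor HIF-2 alpha), Plcxd1 and Unc13a rose by between 3.48 and 5.02.

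Among the 12 genes with the largest fall, 4 encoded cytokines. Il2, the main growth factor of activated T cells, had 27.9 and 12.4 CPM in WT libraries and 1.91 and 1.29 CPM in KO libraries (-3.65 ± 0.49, adjusted p = 0.0303). Il22 (-3.69 ± 0.56), Lta, which encodes lymphotoxin alpha (-2.69 ± 0.21), and Ifng, which encodes interferon gamma (-2.48 ± 0.20), fell as well. Ifng (chromosome 10, 118441046 to 118445892) stood at 215 and 280 CPM in WT libraries and at 48.2 and 40.8 CPM in KO libraries (adjusted p = 0.0176). The largest fall was that of Abca1, which exports cholesterol from cells, from 68.8 and 21.4 CPM to 1.63 and 2.80 CPM (-4.35 ± 0.62, adjusted p = 0.0327). The others were Hba-a2 (an alpha globin with a near-identical copy, -4.01), Crabp2 (a binding protein of retinoic acid, -3.72), Jchain (the joining chain of secreted antibodies, -3.60), Apol7c (-3.54), the interferon-induced Isg15 (-2.88), Utf1 (-2.56) and Spi1, a transcription factor of myeloid and B cells (-2.52).

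**Figure D1:**
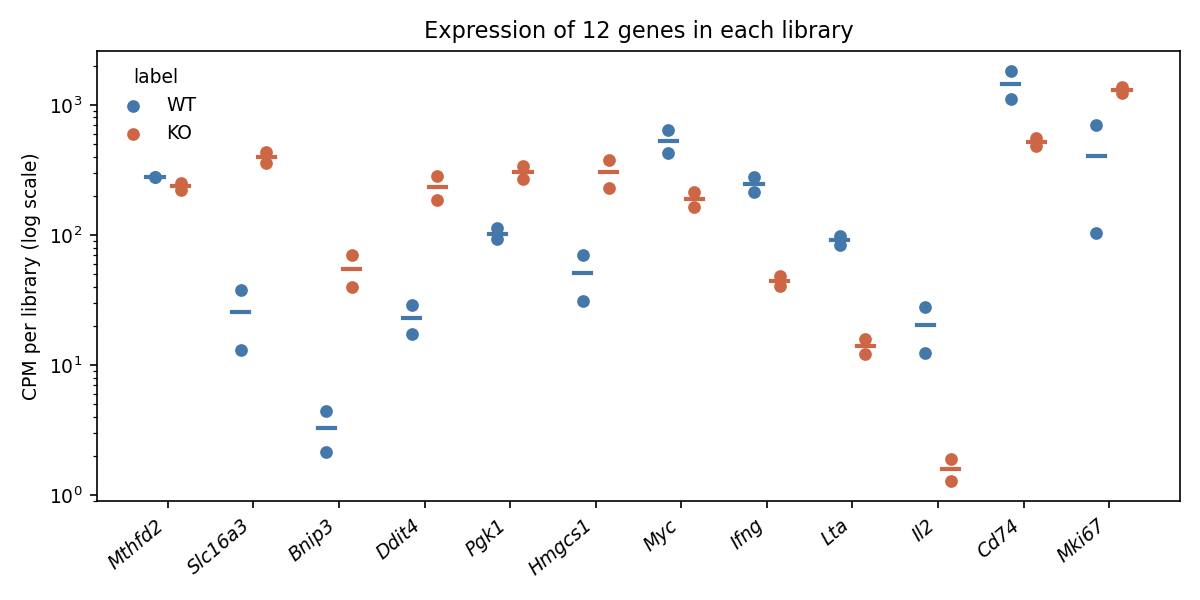
Expression of 12 genes in each library, as CPM on a log axis, with 1 point per library, blue for WT and orange for KO, and a bar at the mean of each group (n = 2). Mthfd2 lies between 222 and 280 CPM in all libraries, Slc16a3 rises from at most 37.7 to at least 359 CPM, and Ifng falls from at least 215 to at most 48.2 CPM. Mki67 is lowest in WT replicate 1 (103 CPM), with 704 CPM in WT replicate 2 and at least 1225 CPM in KO libraries.

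Genes of glycolysis and lactate export rose together in KO libraries. Of 22 members tested, 17 rose, 0 fell and 5 were not called (18 rose and 0 fell adjusted over the list alone), and the median log2 fold change was 1.21. The called genes covered glucose uptake (Slc2a1, 1.42, and Slc2a3, 2.33), the steps from Hk1 (1.31) to Pkm (1.12) except that of Gapdh, and lactate production and export (Ldha, 1.01, and Slc16a3). Pgk1, phosphoglycerate kinase, rose from 102 ± 14.1 to 302 ± 49.2 CPM (SD, n = 2 each) and Tpi1 by 2.03 ± 0.28. Pdk1, the kinase that restrains entry of pyruvate into mitochondria, rose by 1.71 ± 0.18. Hk2 (0.32, adjusted p = 0.246) and Gapdh (0.68, adjusted p = 0.0949) did not pass. Several of these enzymes have processed copies that can share reads. The list was called by camera (adjusted p = 1.27e-10), and with an estimated correlation its adjusted p was 0.736.

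Hypoxia-responsive genes also rose. Of 19 members, 13 rose and 0 fell (17 rose and 1 fell adjusted over the list alone), with a median of 1.81. Egln1, an oxygen-sensing prolyl hydroxylase, rose from 85.1 ± 9.90 to 299 ± 17.7 CPM, and Bnip3l, a receptor for the removal of mitochondria, by 2.51 ± 0.20. Ddit4, an inhibitor of the growth kinase complex mTORC1, rose from 23.1 ± 8.23 to 234 ± 67.3 CPM. Hif1a itself stood at -0.04 ± 0.16 (adjusted p = 0.907), Vegfa at 1.23 ± 0.31 (adjusted p = 0.0711), and Adm at -2.34 ± 0.62 (adjusted p = 0.0808). The list was called by camera (adjusted p = 1.77e-10), and with an estimated correlation its adjusted p was 0.736. Slc2a1 and Pdk1 are in both this list and the glycolysis list. The medians of these lists without WT replicate 1, the library that lay apart, were 1.70 for hypoxia and 1.02 for glycolysis, with 14 and 15 members called, and in the same fit the median of the MHC class II genes of other cells was -0.96.

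Genes of cholesterol synthesis rose in part. All 20 members had a positive log2 fold change, 11 rose over all genes tested and 20 adjusted over the list alone, and the median was 2.01. Hmgcs1, an early enzyme of the pathway (chromosome 13, 119690379 to 119708260), rose from 51.0 ± 27.8 to 303 ± 105 CPM (2.57 ± 0.42, adjusted p = 0.0400). Fdft1 rose by 2.21 ± 0.34, Msmo1 by 2.51 ± 0.38 and Lss by 1.90 ± 0.30. The list was called by camera (adjusted p = 1.27e-10), and with an estimated correlation its adjusted p was 0.736. The list median was 19.3 CPM in WT replicate 1 and 42.6 CPM in WT replicate 2, and 17 members were called without WT replicate 1 and 20 without WT replicate 2. With all libraries, 7 were called with upper quartile factors, 17 by limma-voom and 18 by DESeq2.

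**Figure D2:**
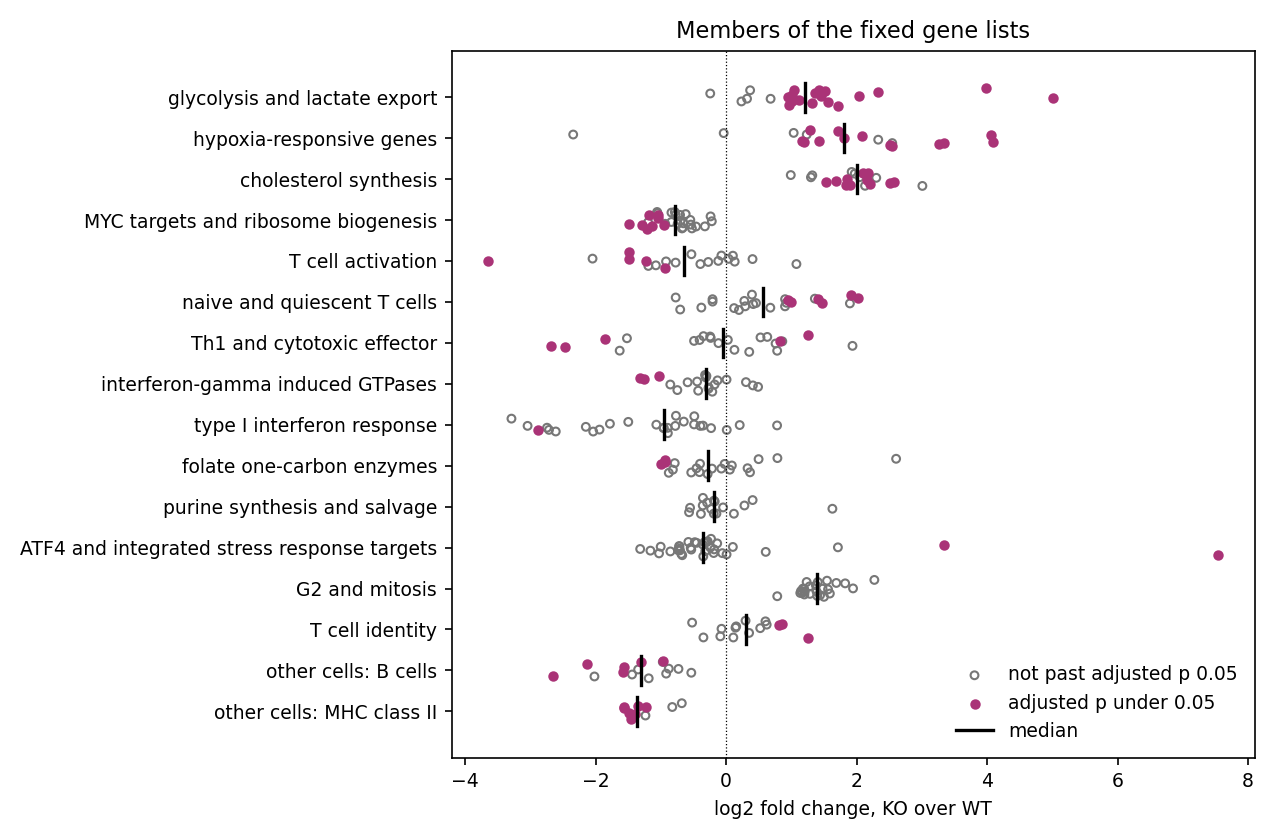
Log2 fold changes, KO over WT, of the tested members of 16 of the fixed gene lists, with 1 point per gene, filled where its adjusted p was under 0.05, and a bar at the list median. Medians run from -1.37 for MHC class II genes to 2.01 for cholesterol synthesis, and the members of G2 and mitosis all lie above 0 with 0 called.

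Targets of MYC and genes of ribosome biogenesis fell in part. All 30 members had a negative log2 fold change, 8 fell over all genes tested and 26 adjusted over the list alone, with a median of -0.78. Myc, the growth-promoting transcription factor, fell from 531 ± 147 to 190 ± 36.6 CPM (-1.49 ± 0.24, adjusted p = 0.0397). Nop2, Rrp9 and Ppan, which process ribosomal RNA, fell (-1.13, -1.21 and -1.18). The list was called by camera (adjusted p = 1.27e-10), and with an estimated correlation its adjusted p was 0.736. The B cell list, whose cells also express these genes, had a median of -1.30 in the same comparison. Without WT replicate 1 the median of the MYC list was -0.77 with 3 members called, and without WT replicate 2 it was -0.83 with 20 called. With all libraries, 5 were called with upper quartile factors, 13 by limma-voom and 25 by DESeq2. Of 50 cytosolic ribosomal protein genes, which share reads with many pseudogenes, 1 fell (Rpl10a, -0.78) with edgeR over all genes, 0 adjusted over the list alone and 2 with DESeq2, and the list was not called (adjusted p = 0.262).

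In folate one-carbon metabolism, the pathway of Mthfd2, 3 of 21 genes fell and 0 rose (6 and 0 adjusted over the list alone). DESeq2 called 6 lower. The 3 genes were the folate carriers Slc19a1 (198 ± 15.7 to 99.7 ± 16.5 CPM, -0.99 ± 0.17, adjusted p = 0.0400) and Slc25a32 (-0.94), which brings folate into mitochondria, and Fpgs (-0.93), which adds the glutamate tail that retains folate. The list as a whole was not called (median -0.28, adjusted p = 0.0757), but it was called without KO replicate 1 (adjusted p = 0.0250). The B cell list (median -1.30) and the MHC class II list (median -1.37) were lower in the same libraries. The edgeR test called 0 members in serine and glycine supply (12 genes, 1 higher and 4 lower at an unadjusted p under 0.05, list adjusted p = 0.187), and DESeq2 called 1 lower. In purine synthesis and salvage (16 genes, median -0.19) edgeR and DESeq2 called 0, with 2 higher and 1 lower at an unadjusted p under 0.05 (list adjusted p = 0.329). In the methionine cycle and DNA methylation (13 genes) edgeR called 0, with 2 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 2 lower (list adjusted p = 0.616). Of 15 genes of pyrimidine and deoxynucleotide synthesis, DESeq2 called 1 higher and 2 lower, limma-voom 2 lower, and edgeR adjusted over the list alone 1 higher and 2 lower. Over all genes edgeR called 1 lower, the deaminase Dctd (49.7 and 49.5 CPM in WT against 23.0 and 26.6 CPM in KO libraries, adjusted p = 0.0400). Its median (0.15) and mean (0.06) were positive while camera put the list lower (adjusted p = 0.795).

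Targets of ATF4 and the integrated stress response, which report on amino acid shortage and mitochondrial stress, gave 2 calls among 35 genes, both higher (2 also adjusted over the list alone), and DESeq2 called 3 higher and 4 lower. The 2 of edgeR were Ddit4 (3.34 ± 0.32) and Vldlr, with 0 and 2 counts in WT and 244 and 138 in KO libraries, and Ddit4 is also in the hypoxia list. The rest leaned lower: 29 of 35 members were negative, the median was -0.36 and the mean -0.07. Camera called the list lower (adjusted p = 0.0221), and with an estimated correlation its adjusted p was 0.768. The call was lost without WT replicate 1 (adjusted p = 0.477) and without KO replicate 2 (0.159). In the same libraries the B cell and MHC class II lists had medians of -1.30 and -1.37.

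T cell activation genes fell in part. Of 20 members, 5 fell and 0 rose (10 fell and 1 rose adjusted over the list alone), with a median of -0.65. They were Il2, Myc, Irf4, a transcription factor induced by receptor signalling (1026 ± 163 to 437 ± 92.0 CPM), Nfkbid (-1.48), a nuclear regulator of NF-kappaB, and the kinase Pim1 (-0.93). The list was called by camera (adjusted p = 0.00174), and with an estimated correlation its adjusted p was 0.736. Genes of naive and quiescent T cells in part moved the other way: 6 of 24 rose and 0 fell (11 rose and 1 fell adjusted over the list alone), with a median of 0.57. Tcf7, the transcription factor TCF-1, rose from 312 ± 36.3 to 625 ± 87.0 CPM. Rasgrp2 (1.91) and Btg2 (1.40) rose as well. The list was called by camera (adjusted p = 0.000722), and with an estimated correlation its adjusted p was 0.736. In the same libraries the B cell list (median -1.30) and the MHC class II list (median -1.37) were lower, and B cells also express Myc, Irf4 and Pim1. Without WT replicate 1, 6 activation genes fell and 10 naive genes rose, and without WT replicate 2, 8 activation genes fell while 10 naive genes rose and 4 fell. DESeq2 called 10 activation genes lower and 1 higher, and 10 naive genes higher and 1 lower.

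Effector genes of Th1 and cytotoxic cells split. Of 22 members, Ifng, Lta and Tnf fell (3 genes, Tnf by 1.86 ± 0.29), while the chemokine receptor Cxcr3 (1.26 ± 0.21) and the signal transducer Stat4 (0.82 ± 0.16) rose. With upper quartile factors or library size only, 1 rose and 3 fell. Adjusted over the list alone, 6 rose and 6 fell, and the list was not called (adjusted p = 0.673). Genes induced by interferon gamma gave 3 falls and 0 rises among 20 members (4 and 0 adjusted over the list alone): Socs1, an inhibitor of cytokine signalling (-1.27), and the GTPases Gbp5 (-1.04) and Irgm1 (-1.33). That list was called lower by camera (median -0.31, adjusted p = 0.0182), and with an estimated correlation its adjusted p was 0.768. The call was lost without WT replicate 1 (adjusted p = 0.288) and without KO replicate 2 (0.0568). Of 27 genes of the type I interferon response, 1 fell, Isg15 (13.9 ± 7.17 to 1.89 ± 0.233 CPM), and 11 fell adjusted over the list alone, with 0 lower by limma-voom and 9 by DESeq2. The median was -0.96, the list was called by camera (adjusted p = 6.97e-05), and with an estimated correlation its adjusted p was 0.736. Without WT replicate 1, in which these genes had a median of 21.2 CPM against 8.86 CPM in WT replicate 2, the median was -0.42. Without WT replicate 2 it was -1.46 with 17 genes lower. The MHC class II list, with a median of -1.37, was lower in the same libraries.

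The medians of the cell cycle lists were lowest in WT replicate 1, and those of WT replicate 2 also lay below both KO libraries. The median of 25 genes of G2 and mitosis was 17.6 CPM in WT replicate 1, 109 CPM in WT replicate 2, and 170 and 176 CPM in the KO libraries. Mki67, a marker of dividing cells, stood at 103 and 704 CPM in WT and 1225 and 1374 CPM in KO libraries (1.69 ± 0.74, adjusted p = 0.212). All 25 members had a positive log2 fold change (median 1.39) and 0 were called by edgeR, 0 adjusted over the list alone and 0 by DESeq2, while 5 had an unadjusted p under 0.05. There were 5 called without WT replicate 1 (median 0.61) and 25 without WT replicate 2. Camera called the list higher (adjusted p = 9.27e-06), and with an estimated correlation its adjusted p was 0.736. S phase genes (30 members, 0 called by edgeR or DESeq2, 1 higher at an unadjusted p under 0.05, median 0.40) were called higher by camera (adjusted p = 0.00504), and with an estimated correlation the adjusted p was 0.781. Replication-dependent histones (21 members, 0 called by edgeR or DESeq2, 2 higher at an unadjusted p under 0.05, median 0.88) were likewise called (adjusted p = 0.00648), and with an estimated correlation the adjusted p was 0.740. Both calls were lost without WT replicate 1 (adjusted p = 0.801 for S phase and 0.739 for histones), and that of S phase also without KO replicate 2 (0.125).

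**Figure D3:**
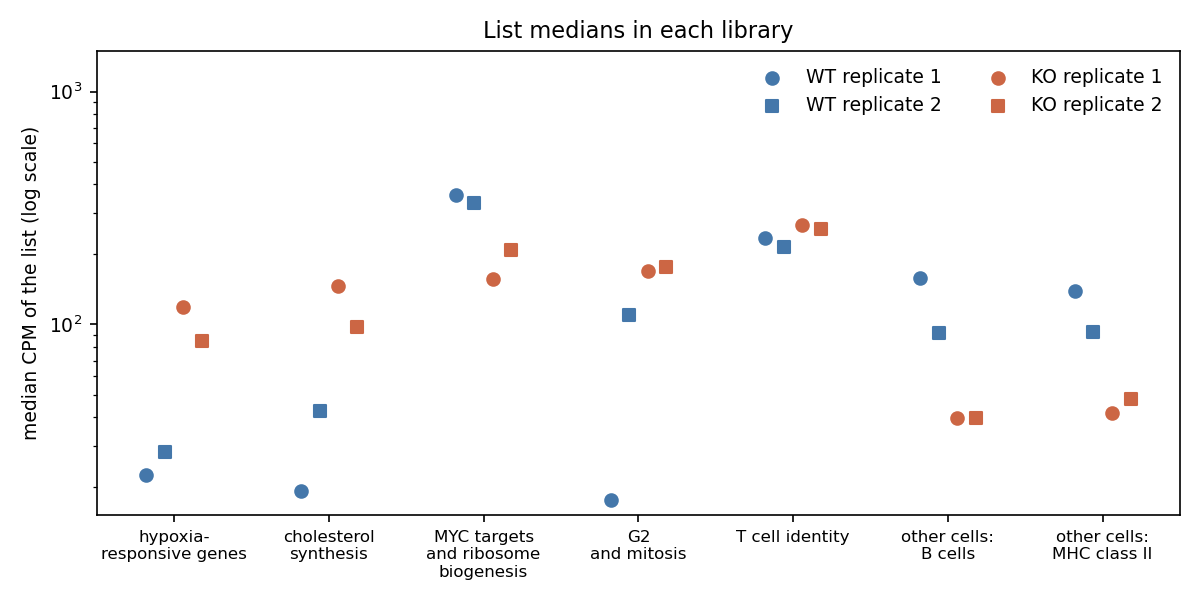
Median CPM of 7 gene lists in each library, on a log axis, with circles for replicate 1 and squares for replicate 2, blue for WT and orange for KO. The G2 and mitosis median is 17.6 CPM in WT replicate 1 against at least 109 CPM in the other libraries, and the B cell and MHC class II medians are highest in WT replicate 1 (158 and 139 CPM) and at most 47.8 CPM in both KO libraries.

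Lists of mitochondrial genes showed small shifts and 0 called members by edgeR, over all genes tested or adjusted over the list alone. In the same libraries the median was -1.30 for B cell, -1.37 for MHC class II and 0.30 for T cell identity genes. Mitochondrially encoded mRNAs (13 genes) had a median of 0.44 and made up 1.59% and 2.09% of WT counts and 2.47% and 2.18% of KO counts. Camera called them higher (adjusted p = 0.00611), and with an estimated correlation the adjusted p was 0.736. At an unadjusted p under 0.05, 5 of them were higher, and DESeq2 called 3 higher. Nuclear-encoded subunits of oxidative phosphorylation (46 genes, median 0.15) were called higher (adjusted p = 0.0178) and mitochondrial translation (30 genes, median -0.29) lower (adjusted p = 0.00611), each with an adjusted p of 0.736 with an estimated correlation. At an unadjusted p under 0.05, 3 of the former were higher and 7 of the latter lower, and DESeq2 called 0 and 1. Without WT replicate 1 the calls of mitochondrially encoded mRNAs and of oxidative phosphorylation were lost (adjusted p = 0.183 for each), and the latter also without KO replicate 2 (0.146). The call of mitochondrial translation was lost without KO replicate 1 (adjusted p = 0.0565).

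Transcripts of B cells, antigen-presenting cells and erythroid cells were in part lower in KO libraries, while the lists of NK cells and CD8+ T cells were not called. Of 15 B cell genes, 6 fell and 0 rose (14 and 0 adjusted over the list alone, median -1.30), and of 10 MHC class II genes, 7 fell and 0 rose (9 and 0, median -1.37). Cd74, the class II invariant chain, stood at 1810 and 1100 CPM in WT and 556 and 485 CPM in KO libraries (-1.48 ± 0.25, adjusted p = 0.0400), and Igkc, the kappa light chain of antibodies, at 762 and 323 CPM against 129 and 119 CPM. Plasma cell genes (3 of 8 fell, 4 adjusted over the list alone, median -1.27), macrophage and monocyte genes (1 of 6 fell, Mpeg1, -2.19; 2 adjusted over the list alone, median -0.95), dendritic cell genes (1 of 8 fell, Ccl22, -1.40; 6 adjusted over the list alone, median -1.29) and erythroid and platelet genes (2 of 7 fell, 5 adjusted over the list alone, median -4.01) were lower too. Camera called these 6 lists, with adjusted p between 1.28e-06 for B cells and 0.0327 for macrophages, and each had an adjusted p of 0.736 with an estimated correlation. Without WT replicate 1 the medians of B cell, class II and macrophage genes were -0.80, -0.96 and -0.36. With upper quartile factors 2 B cell genes, 3 class II genes and 1 dendritic cell gene fell, while 0 plasma cell, macrophage and erythroid genes were called by edgeR, and limma-voom also called 0 in those 3 lists, against 4, 2 and 4 with DESeq2 and 4, 2 and 5 adjusted over the list alone. With library size only, 4 B cell, 6 class II, 1 plasma cell, 0 macrophage and 1 erythroid genes fell. Without KO replicate 2 the calls of macrophages (adjusted p = 0.147), dendritic cells (0.228) and erythroid cells (0.0568) were lost. Of 8 NK cell genes, 2 rose and 0 fell (3 and 1 adjusted over the list alone, median 0.66), namely Klrk1 (1.76 ± 0.35) and Klrd1 (1.70 ± 0.31), but 0 NK cell genes were called by edgeR with upper quartile factors or library size only, against 2 with limma-voom and 3 with DESeq2. The list was not called (adjusted p = 0.439). Of 6 CD8 T cell genes, edgeR called 0 and DESeq2 called 1 higher, with 1 higher and 1 lower at an unadjusted p under 0.05 (1 higher adjusted over the list alone, median 0.38), and the list was not called (adjusted p = 0.416). No neutrophil gene passed the filter, and of 15 matched macrophage and monocyte genes 6 did. With 5 of those 6 not called by edgeR, the macrophage and monocyte list rests on few genes.

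T cell identity genes were in part higher in the same libraries. Of 15 members, the CD3 chains Cd3g (1.26), Cd3d (0.86) and Cd3e (0.81) rose and 0 fell (5 rose and 1 fell adjusted over the list alone), with a median of 0.30. Camera called the list (adjusted p = 0.0327), and with an estimated correlation its adjusted p was 0.736. The call was lost without WT replicate 1 (adjusted p = 0.0974), WT replicate 2 (0.0694) or KO replicate 2 (0.149). Cd4, the co-receptor named by the labels, stood at 134 and 153 CPM in WT and 174 and 193 CPM in KO libraries (0.35 ± 0.15, adjusted p = 0.209). Cd8a, the co-receptor of the other main T cell lineage, stood at 536 and 474 CPM in WT and 550 and 616 CPM in KO libraries (0.21 ± 0.15, adjusted p = 0.423), or between 3.10 and 4.00 times the level of Cd4 in every library. Trbv19, the beta segment of the TEa receptor, held between 6.37% and 8.39% of Trbv counts. H2-Ea, the BALB/c chain that TEa cells recognise, had 2 counts in WT replicate 1 and 0 in the other libraries.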

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

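The setting legacy=FALSE and the counts of list members were added after the data were seen, and the other alternatives were fixed before. No called gene changed sign under any setting, but this was nearly fixed in advance. In all 504 called genes both KO libraries lay on 1 side of both WT libraries. Against 305 higher and 199 lower genes, the lower count moved to 122 with upper quartile factors and to 317 with edgeR's legacy=FALSE. Both moved to 737 and 682 with no filter on low counts, where 18347 genes were tested, and to 854 and 779 with DESeq2; the causes were not tested beyond the number of genes. At an adjusted p under 0.01 edgeR called 0 higher and 0 lower, with 3250 genes at an unadjusted p under 0.05. Leaving out 1 library in turn gave between 0 and 1423 higher and between 0 and 1101 lower genes, both 0 without either KO library, where the lone KO sample is assumed to vary like the WT pair and the median SE of the 305 higher genes was 0.28 against 0.21. The replicate numbers do not pair the samples by the labels, and the deviations of same-numbered libraries had a correlation of 0.04; with the number as a replicate block edgeR called 488 higher and 401 lower genes and camera the same number of lists. Mthfd2 stayed uncalled in every setting, with log2 fold changes between -0.33 and -0.15. Of 22 called lists, 0 were called with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by fry (5), and with 1 library left out between 14 (without KO replicate 2) and 25 lists were called in all, of which between 14 and 21 were among the 22. Without WT replicate 1 the members called numbered 17 for cholesterol synthesis (11 with all libraries), 3 for MYC targets (8) and 10 for naive T cells (6); fewer samples entered, and the cause was not tested further.

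Over all alternatives, named genes kept direction and side of the threshold 1707 times, lost the call 188 times and gained it 156 times, and lists kept it 312 times, lost it 61 times and gained it 4 times. Among named genes the direction turned for Ccr2, not called in any setting, at 0.27 with all libraries and between -0.39 and 0.72 with 1 left out. Lists that were not called turned direction with 1 library left out, with adjusted p between the following bounds over the libraries left out. They were pyrimidine synthesis (0.284 to 0.773), p53 targets (0.316 to 0.837, and 0.992 with shared members left out), the BCL2 family (0.347 to 0.868), inhibitory receptors (0.316 to 0.834), purine synthesis (0.114 to 0.990), the methionine cycle (0.285 to 0.810), regulatory T cells (0.0304 to 0.709), Th1 (0.340 to 0.706), Th2 (0.00536 to 0.968) and Th17 (1.78e-05 to 0.575). The cause was not tested. Between 14191401 and 15955863 counts in each of 2 libraries per group may limit how many changes are called. In the simulation, which differed from the libraries in its spread and share of changed genes, 35.1% of 2-fold changes were called.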

Other observations

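All tests of explanations given here were chosen after the results were seen, while the gene lists were fixed before. Single genes of further T cell and survival lists were called, while the lists themselves were not. Among 17 genes of the BCL2 family and caspases, the death-promoting Bcl2l11 (BIM) rose by 1.12 ± 0.16, while the survival gene Bcl2l1 (BCL-XL, -0.98 ± 0.17) and the death-promoting Bid (-0.82 ± 0.15) fell (edgeR, Benjamini-Hochberg adjusted p = 0.0326, 0.0400 and 0.0414). The list was not called (adjusted p = 0.609). Of 18 targets of p53, Btg2 rose and Aen fell by 0.85, and of 17 NRF2 and oxidative stress genes 0 were called by edgeR and 0 by DESeq2, with 6 at an unadjusted p under 0.05. The list adjusted p were 0.760 and 0.329. Among 18 inhibitory receptor and exhaustion genes, Pdcd1 (PD-1) rose from 33.8 and 49.4 CPM to 99.2 and 86.4 CPM and Nr4a3, a gene induced by receptor signalling, fell by 1.80 ± 0.25. Among 12 follicular helper genes Pdcd1 rose and Pou2af1 fell by 1.22, among 20 regulatory T cell genes Nrp1 rose by 1.28, and among 13 Th17 genes Il22 fell. The B cell list, with a median of -1.30, was lower in the same libraries, and which cells held the Pou2af1 transcripts was not tested. The call of Pdcd1 was lost with upper quartile factors and with library size only, and that of Aen with upper quartile factors. Adjusted over the list alone, 3 rose and 6 fell among regulatory T cell genes, 3 and 3 among inhibitory receptors and 1 and 3 among follicular helper genes. Of 11 Th2 genes, 0 were called by edgeR, 1 had an unadjusted p under 0.05 and DESeq2 called 1. None of these T cell lists was called (adjusted p between 0.280 and 0.670), but without KO replicate 1 the lists of Th17 (1.78e-05), Th2 (0.00536) and regulatory T cells (0.0304) were called lower.

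Low cell sterol was tested as a hypothesis for the rise of cholesterol synthesis genes, since sterols drive the receptor LXR. Of 5 genes induced by LXR, the sterol exporters Abca1 (-4.35 ± 0.62) and Abcg1 (-2.10 ± 0.40) fell, Smpdl3a rose (2.05 ± 0.29), and Mylip (-1.72 ± 0.47) and Lpcat3 (0.40 ± 0.16) were not called. Their median, -1.72, is the value of Mylip and decides nothing over members that go both ways, so the hypothesis stays open.

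The rise of hypoxia and glycolysis genes, and of cholesterol synthesis genes, was set against the makeup of the samples. If KO libraries only held fewer other cells, T cell identity genes would rise as much, but their median lay lower on the log2 scale. The difference was -1.07 from hypoxia and glycolysis genes (bootstrap 95% interval -1.57 to -0.64, 10000 draws over genes) and -1.71 from cholesterol synthesis genes (-2.03 to -1.31). These intervals take the genes of a list as independent and do not cover the spread between libraries. The raised lists were taken up after their medians were seen, so the sign of each difference was known beforehand. Among 15 identity genes, Cd3g (1.26), Cd3d (0.86) and Cd3e (0.81) lay above the median of 0.30, while 4 were negative. The comparison bears only on an even loss of other cells, and a shift among kinds of T cells was not tested. If WT replicate 1 alone made the rise of hypoxia and glycolysis genes, it would shrink without that library, but the median of the 39 genes was 1.24 without it and 1.37 with it. Denser or more actively dividing KO cultures, which use up oxygen, may also raise such genes, and this was not tested. The deletion of Mthfd2, which the design names, remains open as a biological hypothesis.

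The lower transcripts of B cells, plasma cells, class II, macrophages and dendritic cells may reflect fewer antigen-presenting cells left after culture in the KO samples. That all 5 lists had a negative median restates the pattern and does not test this. Fewer antigen-presenting cells and lower expression in such cells therefore cannot be told apart. For class II, H2-Ea had 2, 0, 0 and 0 counts against 8817, 4458, 2437 and 2056 of H2-Eb1. These counts argue against the labelled F1 cells as the main source of class II reads, if reads of H2-Ea are counted when present. Scaling of the libraries moves all genes alike, but the median of the 47 genes of these lists differed from that of T cell identity genes by -1.60 (bootstrap 95% interval -1.97 to -1.27), which no scaling factor changes. The interval covers the spread between genes, not that between libraries. The deletion of Mthfd2 remains open as a biological hypothesis.

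The high level of Cd8a and the T cell receptor segments went against the labels of a CD4+ TEa population in every library. The TEa receptor uses Trav14 and Trbv19, but Trbv19 held 7.39% (95% interval 6.35% to 8.55%) and 8.39% (7.27% to 9.63%) of Trbv counts in WT and 6.37% (5.62% to 7.19%) and 7.37% (6.51% to 8.31%) in KO libraries, at most 8.39%, with 15 or 16 segments at 2% or more, which restates the pattern and does not test whether T cells with many receptors are its source. CD8+ T cells carried along with the antigen-presenting fraction could be lost in step with its B cells. Cd8a and Cd8b1 would then fall in KO libraries like B cell and class II genes (upper quartile -0.97). Instead Cd8a (474 to 616 CPM) stood at 0.21 with a lower 95% bound of -0.15. Cd8b1 (262 to 417 CPM) stood at 0.56 with a lower bound of 0.23. These values argue only against such a joint loss. CD8+ T cells of that fraction may last differently from B cells, which was not measured, so this source stays open. Class II reads from F1 donors would bring H2-Ea, which C57BL/6 mice do not express, but it had 2, 0, 0 and 0 counts against 8817, 4458, 2437 and 2056 of H2-Eb1, at most 0.0227%, if reads of H2-Ea are counted when present. Whether the cultures held polyclonal T cells of both lineages, though positive selection for CD4 would remove CD8+ ones, or whether the labels describe other cells, stays open.

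Ddx3y, a gene of the Y chromosome, had 2146 and 1367 counts in WT and 1152 and 1127 in KO libraries, and Xist, expressed from an inactive X chromosome, had 0, 6, 1 and 0 counts.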
